A study of Caenorhabditis elegans with 2 samples.

How the data were processed

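Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans of strain OP37, which carries the transgene wgIs37 in an unc-119(ed3) background and expresses PHA-4 fused to enhanced green fluorescent protein. Males and females were pooled as young adults, and there were 2 biological replicates in 1 group, each from its own biosample per the labels. Library fragments covered 150 to 350 bp per the labels. The group and replicate numbers were taken from the labels. The read depth of each library, the aligner, the peak caller and the irreproducible discovery rate (IDR) cut-off are not given in the sources used here, so depth is unknown and intervals cover counting error over peaks or genes only.

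The authors deposited peak lists in narrowPeak format on the ce10 and ce11 genome builds. Per the deposited notes that accompany the lists, each replicate had a relaxed list of peaks together with background regions, made as input for IDR from that replicate's alignments and a further file that the notes do not describe, while the labels name a possible control, a further relaxed list was made from the pooled alignments, and the optimal list held the regions that passed IDR. The signal value of each peak is the authors' own value from the deposited lists, and its scaling is not stated. It was therefore used to rank peaks within a list, and between lists only by rank or as a log2 ratio centred on the median peak. The deposited lists also give −log10 of each peak's q value, and the p value column was not filled. Signal tracks and alignments were not used here.

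Coordinates are on ce11, whose chromosome lengths match the reference assembly WBcel235, and are counted from 1. The ce10 lists were used for counts and chromosome shares without converting coordinates. Genes came from the Ensembl release 115 annotation. A peak was assigned to a protein-coding gene when its summit lay between 1000 bp upstream and 200 bp downstream of an annotated transcript 5' end, called the promoter window, and a peak was assigned to every gene whose window held it. Each summit was also placed in 1 class, in the order promoter, coding exon, untranslated exon, intron, non-coding gene and intergenic. Class shares were compared with the same classes over the 6 nuclear chromosomes by exact binomial tests, and chromosome shares with chromosome lengths in the same way. Optimal peaks were compared with the lower 50% of the pooled relaxed list by signal, taken as background-level regions, with Fisher's exact test. Confidence intervals of shares are exact Clopper-Pearson intervals at 95%.

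Replicates were compared by how many of the 839 strongest regions of one overlapped one of the 839 strongest of the other by at least 1 bp, against 1000 random placements on the same chromosomes. Signals were compared across optimal peaks by Spearman and Pearson correlation with 100000 permutations. A set of 10 consensus sequences, called motifs below, was searched on both strands within 100 bp of each summit and in a window of equal size centred 500 bp away on a randomly chosen side, and compared by exact McNemar tests on peaks that held the motif in only 1 of the windows. All 2080 6-mers, counted together with their reverse complements, were tested in the same way. For 22 gene lists, the share of members with an optimal peak in the promoter window was compared with all other protein-coding genes by Fisher's exact test. These other genes were not matched for expression or open promoters. Peak density near pha-4 and unc-119 was compared with the mean of the chromosome by a one-sided exact Poisson test. Other tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each family of tests. Symbols of 3 list members (abu-3, pqn-5 and atg-11) were not matched to the annotation, and the histone list counted 50 of the 72 genes with a his symbol.

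The main tests, the gene lists, the motifs and a rule for the genes named in the text were set before the data were examined. The rule took pha-4 and unc-119, at most 2 genes of each of the 20 strongest optimal peaks that had a gene in the promoter window, up to 4 members per list with the strongest peak, and every member where a list had 5 or fewer with a peak. It also took the 5 optimal peaks with the largest difference between replicates, of those with a region in both. Genes named outside this rule are said to be so.

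The tests were checked on simulated data. In 20 sets of 839 randomly placed peaks, 0 sets gave a called motif, 1 set gave a called gene list, 1 set gave a promoter share with p below 0.05, and 2 6-mers were called over all sets. Random placement gives summit and flank windows no systematic difference in G and C content, unlike the real peaks. These sets thus do not check motif calls against such a difference. A forkhead site planted in 30% of random windows was called with an exact p = 1.04e-13, and both of its 6-mers were called. Peaks placed at 20 ribosomal protein genes led to a call for that list and for 0 other lists. Alternatives covered the genome build, stronger peaks, overlap rules, promoter windows, gene assignment, the background genes, motif windows, shuffled sequences and each replicate alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.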

Results

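PHA-4 is the FoxA-type forkhead transcription factor of C. elegans, which specifies the pharynx in the embryo and is needed in adults for the longer life of worms on a restricted diet. The tagged factor was profiled in whole young adults in 2 biological replicates, to map where it sits in the genome at this stage. The pooled relaxed list held 24890 regions, of which 4065 had a q value of at most 0.05, and each replicate's relaxed list held 30000. The optimal list held 839 peaks, mostly 340 bp wide, and these were exactly the 839 pooled regions with the highest signal values, from 41.0 to 168.7 with a median of 50.8. No untagged or wild-type library was analysed here, so binding levels are not set against a control immunoprecipitation.

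Among the 28 strongest peaks, 20 had a protein-coding gene in the promoter window, and at 8 of these the genes included 1 for a ribosomal protein. The highest signal, 168.7, was on chromosome V at 18967776 to 18967928, where the summit lay 37 bp upstream of Y39B6A.43. The next was 149.9 on chromosome IV at 654757 to 655096, in the shared upstream region of rpl-15, a protein of the large ribosomal subunit, and K11H12.8. It was followed by rpl-3 (142.0, chromosome III at 3867402 to 3867741, 282 bp upstream) and by the peak between rpl-20 and Y17G9B.5 (141.1, chromosome IV at 4749895 to 4750234). Others among the 20 strongest with a gene in the promoter window were at iff-2 and F54C9.14 (122.7), tasp-1 and K01G5.10 (120.6), rps-12 and ska-3 (118.6), sec-61.G and F32D8.13 (117.7), and rps-19 and hsr-9 (117.7). The iff-2 gene encodes a homologue of the translation factor eIF5A, and sec-61.G a subunit of the channel through which new proteins enter the endoplasmic reticulum. Lower in that set were H41C03.3 (116.9), rps-20 and ekl-4 (115.9), drr-2 and set-16 (115.8), cdc-48.1 (114.3), cox-5A (113.0), puf-9 (107.7), rab-18 and kbp-4 (107.2), hsp-1 (100.5), vig-1 (99.1), rpl-11.2 (97.8), and rps-15 and F36A2.9 (97.2). The cdc-48.1 gene encodes a protein-unfolding ATPase, cox-5A a subunit of cytochrome c oxidase, and hsp-1 a constitutive Hsp70 chaperone.

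Peaks were concentrated in promoters and rare in coding sequence. Of the 839 optimal summits, 520 (62%, 95% interval 58.6 to 65.3) lay in the promoter window, which covers 26.2% of the nuclear genome (2.36-fold, adjusted p = 1.51e-103, exact binomial test). Coding exons held 17 summits (2.03% against 18.9% of the genome, adjusted exact p = 3.68e-52) and introns 99 (11.8% against 27.1%, adjusted p = 1.11e-26). Untranslated exons held 2.38% against 2.72% (adjusted exact p = 0.670), and intergenic sequence 19.8% against 21.6% (adjusted p = 0.250), with neither difference past the threshold. Non-coding genes held 2.03% against 3.44% (adjusted exact p = 0.0338), a difference not past the threshold in 5 of 6 alternatives, including both other promoter windows, the stronger peaks and replicate 1 alone (adjusted p from 0.0622 to 0.268). In the promoter window the summit lay a median of 200.5 bp upstream of the nearest 5' end (quartiles 106 and 325), and 482 of 520 summits were upstream of it. In all, 703 protein-coding genes of 19973 had an optimal peak in the window, and 182 peaks had 2 or more genes. Background-level regions of the pooled list were in the window in 30.5% of 12445 cases, so that the odds for an optimal peak were 3.72 times higher (p = 2.93e-73, Fisher's exact test). The promoter share was 62.1% for the 839 strongest peaks of replicate 2 alone and 46.7% for those of replicate 1 alone, whose coding exon share was 12.8%.

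**Figure D1:**
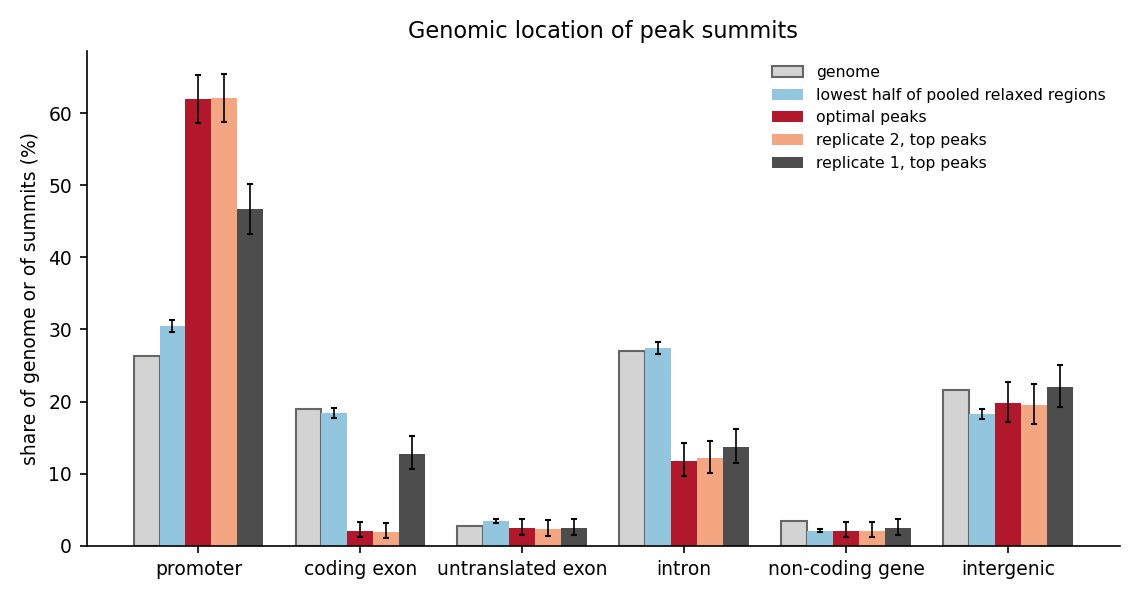
Share of the genome and of peak summits (%, vertical axis) in each of 6 annotation classes (horizontal axis), for the genome, the lower 50% of pooled relaxed regions by signal, the 839 optimal peaks, and the 839 strongest nuclear peaks of each replicate, with exact 95% intervals as error bars. Promoters hold 62% of optimal summits against 26.2% of the genome, and replicate 1 lies between them at 46.7%.

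By chromosome, peaks were more frequent than length predicts on chromosomes III and X and less frequent on IV and V. Chromosome III held 154 peaks (18.4%, 95% interval 15.8 to 21.1, against 13.7% of the nuclear genome, adjusted p = 0.00120, exact binomial test) and X held 178 (21.2% against 17.7%, adjusted p = 0.0172). Chromosome V held 139 (16.6% against 20.9%, adjusted exact p = 0.00572) and IV a share of 14.2% (against 17.4%, adjusted p = 0.0184). Chromosomes I and II, with 114 and 135 peaks, did not pass the threshold. The X share was no longer past the threshold in replicate 2 alone (19.5%, adjusted exact p = 0.241) or replicate 1 alone (17.9%, adjusted p = 0.856), while the share of III was higher than predicted in each (17.5%, adjusted p = 0.0131, and 20.3%, adjusted p = 6.37e-07). The lower shares of IV and V were past the threshold in replicate 1 alone and not in replicate 2 alone (adjusted exact p = 0.380 and 0.0813), and the share of I was higher than predicted in replicate 1 alone (19.2%, adjusted p = 0.00237). No chromosome was past the threshold among the 419 stronger peaks (III 18.1%, adjusted exact p = 0.0767).

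Genes of the ribosome led the 22 gene lists. Of 78 cytosolic ribosomal protein genes, 40 (51.3%, 95% interval 39.7 to 62.8) had an optimal peak in the promoter window, against 3.33% of other protein-coding genes (odds ratio 30.5, adjusted p = 4.05e-36, Fisher's exact test). The strongest were rpl-15, rpl-3, rpl-20 and rps-12, with summits 168 to 351 bp upstream of the gene. With 1 gene per peak, the nearest of those in the window, 20 of the 78 had a peak (odds ratio 13.6, adjusted exact p = 1.14e-13), and with the nearest 5' end also 20 (odds ratio 8.99, adjusted p = 1.53e-10). Among 31 translation factors, 7 had a peak (22.6%, odds ratio 8.07, adjusted exact p = 0.000599). The highest signals in this list were at eif-3.C (88.1), eef-1A.1 (81.0), eef-2 (74.4) and eef-1G (71.6), a subunit of initiation factor eIF3 and elongation factors. The heat shock and unfolded protein response list had 6 of 17 genes with a peak (35.3%, odds ratio 15.1, adjusted exact p = 0.000182). These included hsp-1, hsp-3, an Hsp70 chaperone of the endoplasmic reticulum (63.1), and xbp-1 (82.1) and ire-1 (59.8), the transcription factor and the sensor of a branch of the unfolded protein response.

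Fewer of these genes had a peak among the strongest of replicate 1. With that replicate alone 9 of 78 ribosomal protein genes had a peak (odds ratio 5.74, adjusted exact p = 0.00142), whereas translation factors (3 of 31, adjusted p = 0.177) and the heat shock list (0 of 17) were not past the threshold, and the difference between the replicates was not tested. Only 7 ribosomal protein genes were at least 1000 bp from the next gene upstream, of which 2 had a peak (28.6% against 2.34% of other such genes, odds ratio 16.7, exact p = 0.0108, adjusted p = 0.0594), a count too small to decide.

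Smaller counts were found in lists that did not pass the threshold with the promoter window. In autophagy, 4 of 25 genes had a peak (odds ratio 5.25, adjusted exact p = 0.0588): lgg-1 and lgg-2, which encode the ubiquitin-like proteins of the autophagosome (67.8 and 56.8), epg-5 (52.2) and atg-18 (45.6). This list passed the threshold under 7 of 10 alternatives, most clearly with the nearest 5' end (6 of 25, odds ratio 8.09, adjusted exact p = 0.00201), and in neither replicate alone (adjusted p = 0.16 and 0.24). Of 20 vacuolar ATPase genes, 3 had a peak (adjusted exact p = 0.139), namely vha-1 (78.6), vha-8 (57) and vha-15 (48.3). Nuclear hormone receptors had peaks at 11 of 269 genes (4.09%, adjusted exact p = 1), the strongest being nhr-291 (73.6), nhr-58 (71.3), nhr-57 (63.6) and nhr-42 (59.5). With the nearest 5' end the receptors were past the threshold (20 of 269, odds ratio 2.07, adjusted exact p = 0.0210), and collagens were depleted (0 of 156, adjusted p = 0.0210). Among 17 genes of the insulin, TOR and dietary longevity pathways only akt-2 had one (43.5), among 156 collagens col-38 (52.9) and col-2 (42.9), and among the 50 histone genes counted in the list his-37 (89.8). The annotation held 72 genes with a his symbol, and his-37 was the only 1 of the 72 with a peak. The col-38 peak was shared with rpl-5, a nearer gene named outside the rule. With 1 gene per peak, 0 of 156 collagens had a peak.

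Lists of pharyngeal genes had peaks at pha-4 alone. No optimal peak lay in the promoter window of any of 11 pharyngeal muscle genes (exact 95% upper bound 28.5%), 8 pharyngeal gland genes (36.9%) or 17 abu/pqn genes of the pharyngeal cuticle (19.5%). Of 13 foregut regulators only pha-4 itself had one. The lists for intestine (24 genes), body wall muscle (12), hypodermis and cuticle collagen (19), neurons (19), germline (20), somatic gonad (7), epithelial junctions (12), superoxide dismutases and catalases (8) and ceh homeobox genes (63) also had 0 genes with a peak. With 3.52% of all genes bound, such small lists could not have passed as depleted.

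**Figure D2:**
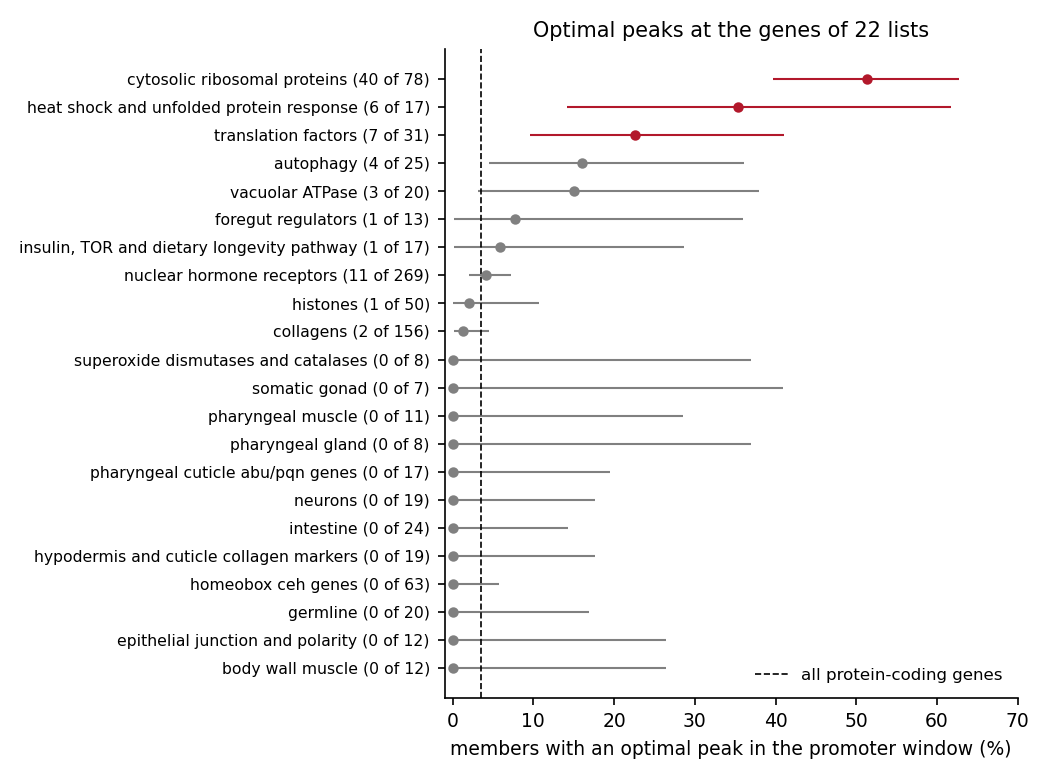
Share of each list's members with an optimal peak in the promoter window (%, horizontal axis), with exact 95% intervals, for 22 gene lists (vertical axis, with counts), and the share over all protein-coding genes as a dashed line. Lists past the adjusted threshold are in red, and the ribosomal protein genes stand highest at 51.3%.

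Sequence at the summits was richer in forkhead sites and GAGA repeats than flanking sequence. The consensus TRTTKRY occurred within 100 bp of 498 summits (59.4%) and in 404 flanks (48.2%). It was present only at the summit for 242 peaks and only in the flank for 148 (ratio 1.64, adjusted p = 5.59e-06, exact McNemar test over 10 motifs). The forkhead family core RYAAAYA was at 45.8% of summits and 33.8% of flanks (adjusted exact p = 1.26e-06), and the GATA site TGATAA, bound by the ELT factors of the gut, at 27.1% and 18% (adjusted p = 1.77e-05). The repeat GAGAGAG was at 17.2% and 2.50% (ratio 9.20, adjusted exact p = 4.35e-25), the E-box CACGTG at 13.1% and 2.98% (ratio 5.25, adjusted p = 2.07e-14), and the E2F site at 2.98% and 0.834% (adjusted p = 0.00263). The homeodomain site TAATTA (4.89% against 10.1%, adjusted exact p = 0.000105) and the heat shock element (10.1% against 16%, adjusted p = 0.000598) were rarer at summits. The SKN-1 core and the nuclear receptor half-site did not pass the threshold (adjusted exact p = 0.749 and 0.327). Summit windows were 41.0% G and C and flanks 35.8%. Against shuffled summit sequence of the same dinucleotide content the forkhead, GATA, E-box and GAGA sites were past the threshold, while the E2F site (2.98% against 3.46%) and the homeodomain and heat shock sites were not.

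The forkhead enrichment did not pass the threshold in replicate 1 alone. Its 839 strongest nuclear peaks held the consensus at 49.6% of summits and 47.6% of flanks (ratio 1.09, adjusted exact p = 0.687), while replicate 2 held it at 61.3% and 45.5% (ratio 1.88, adjusted p = 5.33e-10). The forkhead core, GATA site, E-box and heat shock element were also not past the threshold in replicate 1 alone (adjusted exact p = 0.313, 1, 0.918 and 0.313), and the E2F site in neither replicate alone (adjusted p = 0.687 and 0.0912). The E-box was at 5.36% of summits and 5.01% of flanks in replicate 1 (ratio 1.08), and its ratio was 7.93 in replicate 2. The differences between the replicates were not tested. The GAGA repeat was past the threshold in both, at 9.65% and 5.24% in replicate 1 (ratio 1.90, adjusted exact p = 0.00444) and with a ratio of 8.56 in replicate 2. In background-level regions the forkhead consensus was at 46.1% of summits and 45.5% of flanks (adjusted exact p = 0.623), and the GAGA repeat at 3.77% and 3.01% (ratio 1.26, adjusted p = 0.0112).

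Among all 2080 6-mers, 335 were more frequent at summits and 285 less frequent, over windows that differed in G and C content as given above. Against shuffled summit sequence 208 were more frequent, 134 of them among the 335, and 320 less frequent. GAGAGA led, at 35.5% of summits against 9.30% of flanks (adjusted p = 2.49e-34, exact McNemar test), followed by AGAGAG (31.0% and 7.51%), GACGCA (21.8% and 3.69%), CGTCTC (24.6% and 5.36%) and AGAGAC (27.2% and 7.27%). In replicate 1 alone 48 were more frequent, 42 of them among the 335, led by AGAGAC (20.6% and 7.15%) and CGTCTC (16.6% and 5.72%). No relation of the forkhead share to peak strength was detected, as it was 57.7% in the 168 strongest optimal peaks and 57.5% in the 167 weakest (Spearman rho = -0.04 across peaks, p = 0.292, permutation test).

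**Figure D3:**
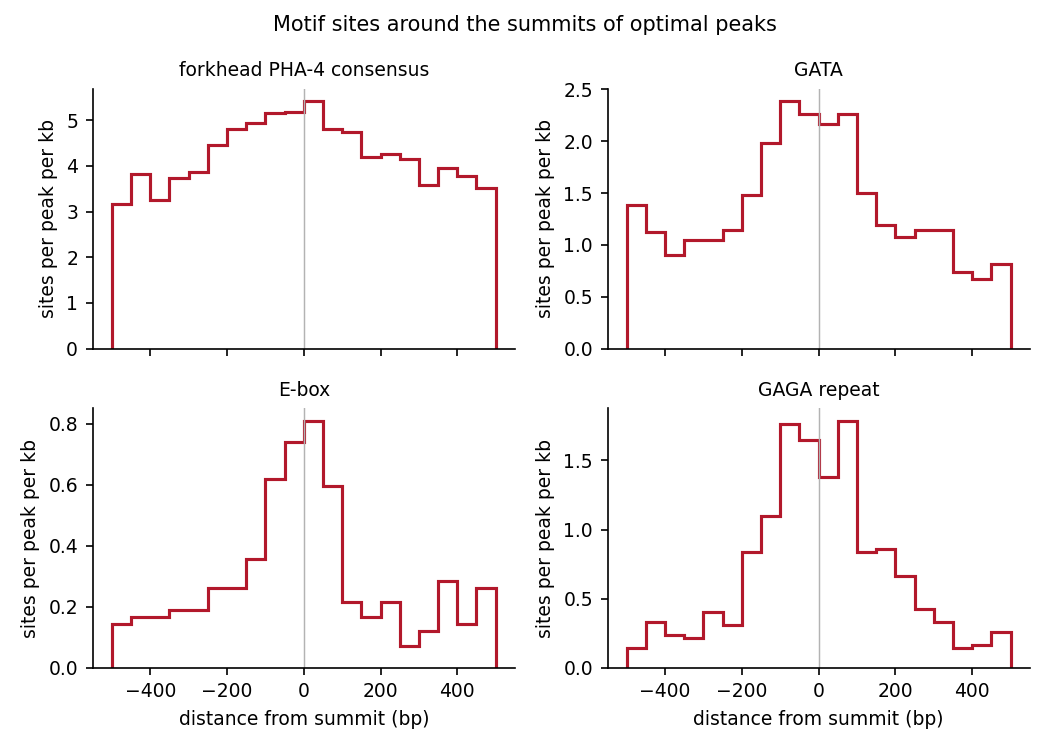
Motif sites per peak and kb (vertical axes) in 50 bp bins by distance from the summit of optimal peaks (bp, horizontal axes), for the forkhead consensus, GATA site, E-box and GAGA repeat. All 4 rise towards the summit, the forkhead consensus over a broad base and the E-box and GAGA repeat more sharply.

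The pha-4 gene itself carried a cluster of peaks. Within 40 kb of the gene (chromosome V, 20753052 to 20760317, plus strand) there were 9 optimal peaks, where 0.580 would be expected from the mean density of the chromosome (15.5-fold, p = 1.21e-08, one-sided exact Poisson test). Of these, 8 lay between 20747963 and 20756949, in the upstream intergenic sequence and in introns near the annotated 5' ends at 20753052, 20755491 and 20756910. The strongest (88.1, 20756610 to 20756949) had its summit 130 bp upstream of the 5' end at 20756910. A forkhead site TATTTGT lay 25 bp from this summit, at 20756802 to 20756808, in the sequence ATTTTCTAAATATTTGTTATTTGTTAT. An intronic peak at 20753895 to 20754234 (58.2) had TATTTGC 9 bp from its summit. Of the 8 peaks, 3 held the consensus within 100 bp of the summit (37.5%), against 59.6% of the other optimal peaks (Fisher's exact p = 0.281). The peak farthest upstream within the cluster, at 20747963 to 20748302 (77.4), lay 4918 bp from the gene. The remaining peak of the 9, at 20728969 to 20729308, was in the promoter window of ipla-3, which was named after its values were seen. Only 2 of the 9 overlapped a region of replicate 1, against 578 of the 830 other optimal peaks (p = 0.00492, Fisher's exact test). The 8 neighbouring peaks at this 1 locus are not independent observations, and the tests here treat them as if they were. In replicate 1 alone 2 of the strongest peaks lay in this 40 kb neighbourhood (4.61-fold, exact p = 0.0708), and in replicate 2 alone 8 (12.9-fold, p = 3.18e-07). At unc-119, the marker gene of the strain, there were 0 optimal peaks within 40 kb, with 0.964 expected, and in replicate 1 alone there were 3 (2.82-fold, one-sided exact Poisson p = 0.0925).

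**Figure D4:**
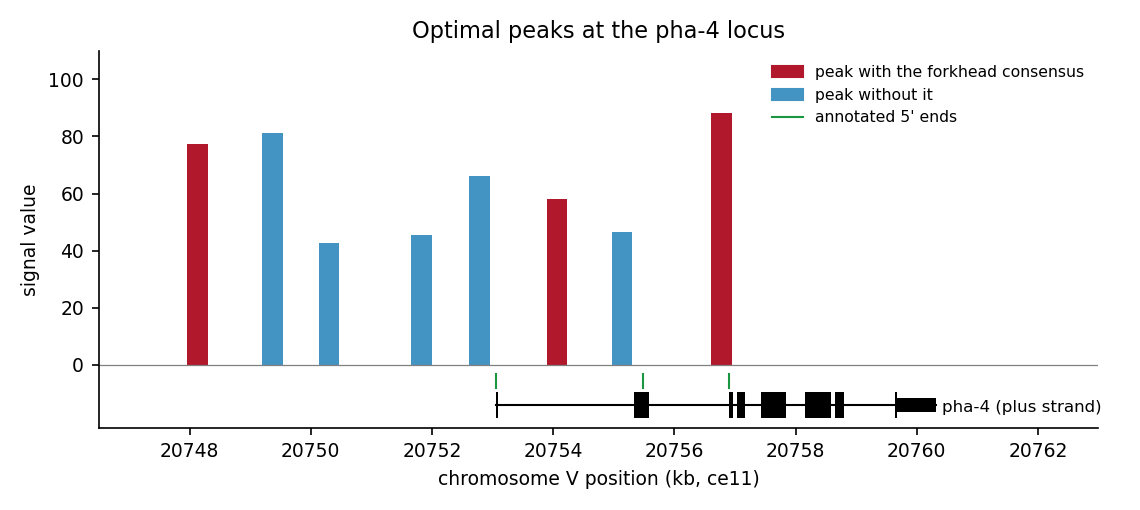
Optimal peaks at the pha-4 locus on chromosome V (position in kb on ce11, horizontal axis), drawn to scale with their signal value (vertical axis), above the exons of pha-4 (boxes, coding parts taller) and its 3 annotated 5' ends. The 8 peaks shown span the upstream region and the introns before the last annotated 5' end, and the strongest reaches 88.1.

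The replicates differed in how many regions had a low q value and shared 13.3% of their strongest peaks. In replicate 2, 7548 regions had a q value of at most 0.05, and in replicate 1 there were 13, all mitochondrial; the lowest q value of a nuclear region of replicate 1 was 0.163. Of the 839 strongest regions of replicate 1, 112 (13.3%) overlapped one of the 839 strongest of replicate 2. Random placement gave a mean of 4.67 and at most 12 (p = 0.001, permutation test, the smallest that 1000 placements can give). Of the optimal peaks, 839 overlapped a region of replicate 2 and 580 (69.1%) a region of replicate 1, where random placement gave a mean of 19.3%. The optimal list was thus not limited to peaks with a region in both replicates. Across these 580 peaks no relation between the signals of the replicates was detected (Spearman rho = -0.05, permutation p = 0.236, adjusted p = 0.236; Pearson r of log2 signal = -0.04, permutation p = 0.345). The pooled signal had a rho of 0.850 with replicate 2 and of 0.176 with replicate 1, and as the pool holds the reads of both, no p is given for these; 3 relations were computed in this family. Peaks are not independent replicates, and they were selected on the pooled signal. The centred log2 ratio of replicate 2 to replicate 1 had an SD of 0.74 across peaks.

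Optimal peaks without a replicate 1 region, such as that at rps-20 (113.7 in replicate 2), have no ratio and were not ranked. Among the 580 peaks with a region in both replicates, the 5 with the largest centred ratio were all higher in replicate 2. They were at Y39B6A.43 (2.67 above the median log2 ratio), cdc-48.1 (2.32), rpl-20 and Y17G9B.5 (2.22), the peak shared by Y71H2AM.20, cox-6B and nduc-2 (2.08), and tasp-1 and K01G5.10 (2.02). The Y39B6A.43 peak ranked 1 in replicate 2 and 23974 in replicate 1. On ce10 the optimal list held 950 peaks, and 136 of the 950 strongest regions were shared between the replicates (14.3%).

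**Figure D5:**
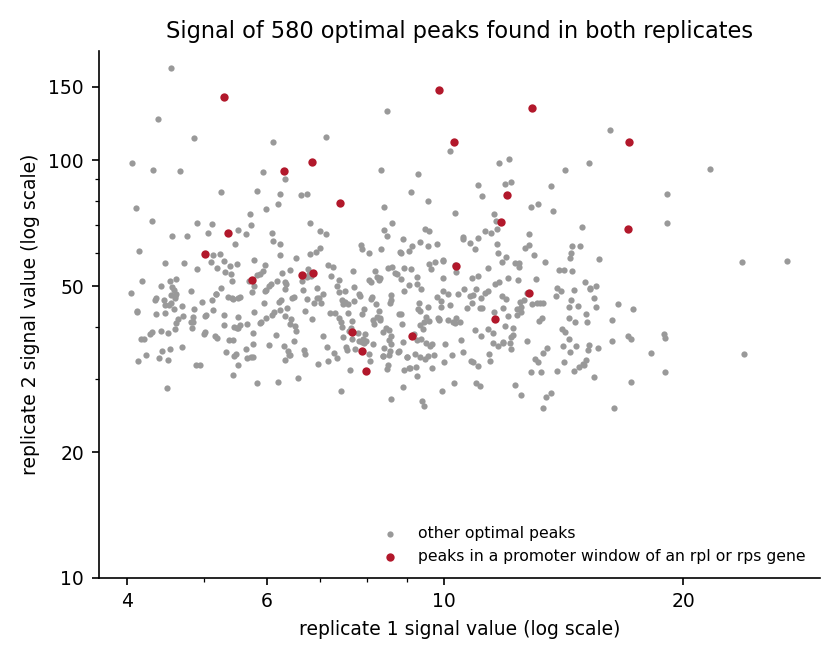
Signal value in replicate 2 (vertical axis, log scale) against replicate 1 (horizontal axis, log scale) for the 580 optimal peaks with a relaxed region in both, with peaks in the promoter window of an rpl or rps gene in red. No trend was detected (Spearman rho = -0.05); the scaling of the values is not stated, so the axes are not compared with each other.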

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

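The tests of the trend along replicate 2's own list and of the forkhead site in replicate 1's unshared peaks were chosen after the results were seen. So were the bound printed for extra copies of the tagged gene and the decision to call the planned test of replicate 1 on optimal peaks void. The replicates' overlap against random placements and the ribosomal protein list in replicate 1 alone were planned tests, but what they would say about an explanation was set after the results were seen. The signal outside the nuclear chromosomes was found only in replicate 1, whose list had 20 mitochondrial regions, while replicate 2 and the pooled list had 0. They held the 19 highest ranks of that list. The strongest, at 8564 to 8893 of the 13794 bp mitochondrial genome, had a signal of 431, against 27 for the strongest nuclear region. They are listed because no comparison is about them, and without them the replicates shared 113 of their 839 strongest peaks.

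The strongest regions of replicate 1 did not lie at random with respect to those of replicate 2. Of its 839 strongest, 112 overlapped one of the strongest of replicate 2, a list made without it, and random placements gave at most 12. These placements were uniform along each chromosome and not matched for promoters. They cannot tell signal of the factor from open promoter chromatin. Whether replicate 1 is a weaker measurement of the sites of replicate 2 was first asked on optimal peaks. There the share with a replicate 1 region changed by -23.7 percentage points from the peaks weakest in replicate 2 to the strongest. This goes against the prediction, which was set before the result was seen. The test was called void only after that, because optimal peaks were selected on the pooled signal. A peak weak in replicate 2 may thus have needed replicate 1 to enter. Over 19848 pooled regions the relation had the other sign but was very weak (Spearman rho = 0.05, no p given), so it does little to settle the question. Over replicate 2's own list the share with a replicate 1 region was 47.9% among the strongest 6000 and 24.3% among the weakest 6000. This difference of 23.6 points is what a weaker measurement predicts, but the comparison did not separate the factor from open promoter chromatin. Open promoter chromatin without the factor stays open as a source of the 726 unshared peaks of replicate 1, of which 44.8% were in promoters: the forkhead consensus was at 48.5% of summits and 47.4% of flanks (p = 0.705, exact McNemar test). No biological explanation was tested, as the labels give both replicates 1 group.

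The cluster of peaks at pha-4 may come from extra copies of the tagged gene or from binding to its own regulatory sequence. Extra copies predict denser regions over the whole inserted segment, and downstream at 5 to 20 kb the pooled list had 0 regions (rate ratio at most 1.17 by the exact 95% interval), but upstream at 5 to 20 kb it had 5 (1.58 times the mean of the chromosome, upper bound 3.69), and the extent of the insert is not known here. Binding predicts forkhead sites: 3 of the 8 peaks within 5 kb had the consensus, against 495 of 831 others (p = 0.281, Fisher's exact test). These 8 are too few to decide, and as neighbours at 1 locus they are not independent. The explanations cannot be told apart here. Within 5 kb replicate 2 had 21 regions (4.78 times the mean of the chromosome, 95% interval 2.96 to 7.30) and replicate 1 had 5 (1.11, 0.360 to 2.58), whereas upstream at 5 to 20 kb replicate 2 had 10 (2.62, 1.26 to 4.82) and replicate 1 had 11 (2.80, 1.40 to 5.02), both above the mean of the chromosome.

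If 1 library decided the enrichment of ribosomal protein genes, it should be lost in replicate 1 alone, and it was not (adjusted exact p = 0.00142). In replicate 1 it rested on 9 of 78 genes (odds ratio 5.74), against 42 of 78 in replicate 2 (odds ratio 34.2). Over 175 symbol families neither rpl nor rps was past the threshold in replicate 1 alone (adjusted exact p = 0.436 for both). Of the 78 genes, 40 had an optimal peak, and 26 had one with a region in both replicates. The test does not show how far each replicate set the optimal peaks at these genes. If the peaks at ribosomal protein genes mark open promoters shared by many factors, rather than forkhead sites, they should hold the consensus less often. It was at 11 of 37 such peaks (29.7%) and at 284 of 483 other promoter peaks (58.8%, p = 0.000854, Fisher's exact test), as that hypothesis predicts. The share was also below that in the flanks of all optimal peaks (48.2%). No flank or shuffled sequence was examined for the 37 peaks by themselves, so the comparison cannot decide for the hypothesis. The GAGA repeat was also rarer at these peaks (1 of 37, 2.70%, against 16.8%, odds ratio 0.138, Fisher's exact p = 0.0185), so the deficit was not particular to the forkhead site. No other factor's peaks were analysed here, so recruitment of PHA-4 by another protein, or weak binding to other sequences, stays open as a biological explanation that was not tested.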

How the results depend on the processing

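The leave-out settings for chromosomes, 6-mers and pha-4, the peaks found in both replicates, the shuffles for 6-mers, the list without mitochondrial regions and the pooled list at q of at most 0.05 were chosen after seeing the data; the others were planned. Of 37 alternatives for main results with a test, 32 kept their direction and side of the threshold; of 16 for counts of peaks, 6-mers or enriched lists, 10 gave a count within 1.5 times the main one, in which single members could still change side. Of 342 for single chromosomes, classes, motifs and lists, 302 kept both. Across its alternatives the promoter enrichment ranged from 1.57-fold to 3.70-fold, and sharing of the strongest peaks from 6.10 to 39.1 times random placement, against 1.68 times for all 30000 regions of each replicate.

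With only the 419 stronger peaks, a list shorter by construction, the X share was 19.3% (adjusted exact p = 0.370). Using each replicate alone, values ranged, among others, as follows: X share 17.9% to 19.5%, share of chromosome I 13.2% to 19.2%, forkhead ratio of summit-only to flank-only peaks 1.09 to 1.88, forkhead core ratio 0.859 to 2.20, GATA ratio 0.992 to 1.91, E-box ratio 1.08 to 7.93, GAGA ratio 1.90 to 8.56, 6-mers more frequent at summits 48 to 329, enriched lists 1 to 3, heat shock list odds ratio 0 to 19.5, and pha-4 neighbourhood 4.61-fold to 12.9-fold. The lower value was that of replicate 1 in each except chromosome I; the cause was not tested beyond the tests of replicate 1 above. In 580 peaks found in both replicates the forkhead ratio was 1.38 (adjusted exact p = 0.0151).

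Against dinucleotide shuffles 208 6-mers were more frequent, 134 of them among the 335, and the E2F ratio was 0.857. Taking the nearest 5' end gave 5 enriched lists in place of 3, and the 4065 pooled regions at q of at most 0.05 gave 7, with an odds ratio of 3.42 for intestine; the longer region list reaches more genes by construction, and for the nearest 5' end the cause was not tested. The autophagy list passed the threshold under 7 alternatives, with adjusted p from 0.00201 to 0.0389. Replicate signals cannot be compared with a replicate left out. The unknown read depth limits what the few regions of replicate 1 with a low q value can show.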

Other observations

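These observations and their tests were chosen after the data were examined, and the genes in them were named after their values were seen, except those named above. The 4065 pooled regions with a q value of at most 0.05, which include all 839 optimal peaks, reached 2555 genes, and 7 lists were enriched. Intestinal genes, none with an optimal peak, had a region in 8 of 24 cases (33.3% against 12.8%, odds ratio 3.42, adjusted p = 0.0215, Fisher's exact test), led by act-5, the microvillar actin (signal 36.8), nhx-2 (36.0) and pept-1, a peptide transporter (34.6), and including the yolk protein genes vit-2, vit-5 and vit-6. Of the insulin, TOR and dietary longevity genes 8 of 17 had one, 1 of them an optimal peak (odds ratio 6.08, adjusted exact p = 0.00216), among them daf-15 (39.8), skn-1 (32.0), aak-2 (29.9), daf-16, the FOXO factor of insulin signalling (27.6), and daf-2, its receptor (23.1). Autophagy had 9 of 25, 4 of them with an optimal peak (adjusted exact p = 0.00845), with hlh-30 (34.4) and unc-51 (22.7) beyond those above, and the vacuolar ATPase 10 of 20, 3 of them with an optimal peak (adjusted p = 0.000276). Collagens were depleted (5 of 156, odds ratio 0.224, adjusted exact p = 0.000276). All lists were compared with genes not matched for open promoters. Enrichment of a list therefore cannot tell targeting by the factor from open promoter chromatin. Pharyngeal muscle and gland had 0 of 11 and 0 of 8 genes, and the abu/pqn list 1 of 17 (abu-8). Of the regions named here, those at act-5, pept-1, vit-5, daf-16, daf-2 and abu-8 overlapped no region of replicate 1. Those at nhx-2, vit-2, vit-6, daf-15, skn-1, aak-2, hlh-30 and unc-51 overlapped one.

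Gene families taken from the symbols alone, 175 with at least 10 members, gave 6 enriched families of optimal peaks. Besides rpl (25 of 47) and rps (15 of 31) these were the galectins (lec, 5 of 12, odds ratio 19.7, adjusted p = 0.00200), cytochrome c oxidase (cox, 5 of 15, odds ratio 13.8, adjusted p = 0.00521), DnaJ proteins (dnj, 6 of 29, odds ratio 7.20, adjusted p = 0.0155) and hsp (5 of 22, odds ratio 8.11, adjusted p = 0.0248), by Fisher's exact test. The galectins were lec-1, lec-6, lec-7, lec-9 and lec-12. In replicate 1 alone 0 of 12 lec and 2 of 15 cox genes had a peak, and none of the 6 families was past the threshold (adjusted exact p = 0.436 for rpl). Windows upstream of snoRNA genes held 27 of 839 optimal summits (3.22% against 0.396% of the genome, 8.12-fold, adjusted p = 6.93e-15, exact binomial test), 6.02-fold in replicate 1 and 6.62-fold in replicate 2. Those of snRNA genes (5.84-fold, adjusted exact p = 0.000646) and miRNA genes (2.89-fold, adjusted p = 0.0228) were also enriched. All of these windows were compared with genome length only. How many of their summits also lay in the promoter window of a protein-coding gene is not given, so a separate enrichment is not shown. The snRNA windows were not past the threshold in replicate 1 (0.834-fold), nor the miRNA windows in replicate 2 (2.07-fold). Pseudogene windows were depleted (0.0972-fold, adjusted exact p = 2.58e-06), and tRNA, piRNA and lincRNA windows did not pass the threshold at optimal peaks.

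Among the leading 6-mers, GACGCA, ACGCAG and CGTCTC, the reverse complement of GAGACG, overlap, and joined they read GAGACGCAG. This 9-mer, on either strand, was within 100 bp of 105 optimal summits (12.5%) and in 4 flanks (0.477%); as it was built from the 6-mers most enriched in these windows, no p is given. It was at 4.53% of summits and 1.19% of flanks in replicate 1 and at 1.21% and 0.828% in background-level regions. Peaks with it had the forkhead consensus less often (41.0% against 62%, odds ratio 0.425, adjusted p = 6.70e-05, Fisher's exact test), the GATA site less often (7.62% against 29.8%, odds ratio 0.194) and the GAGA repeat more often (37.1% against 14.3%, odds ratio 3.54). The 9-mer begins with GAGA and can share bases with the GAGA repeat. Sites without shared bases were not counted, so the last difference may come from the overlap. No difference between promoter peaks (13.5%) and others (11%) was detected (Fisher's exact p = 0.334). GATA sites were at 37% of optimal peaks outside promoters and at 21% in promoters (odds ratio 0.452, adjusted exact p = 6.10e-06). The SKN-1 core, not past the threshold in optimal peaks, was at 24.4% of summits and 17% of flanks in replicate 1 alone (ratio 1.58, adjusted exact p = 0.00216), and at 18.6% and 19.2% in replicate 2 alone; the difference between the replicates was not tested.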
